A study of Triticum aestivum with 32 samples.

How the data were processed

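Flag leaf RNA of the bread wheat cultivar Stettler was sequenced from 8 treatment groups of 4 libraries each, 32 libraries in all. Each library was placed in its group from the source name in the labels, which also gives its replicate number. The series text calls the replicates of a treatment independent biological samples.

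The deposited values are in TPM, a unit that divides the reads of each transcript by its length and then scales each library to a total of 1000000. Per the series text and the submitters' processing notes, the authors aligned filtered reads with STAR and estimated TPM with RSEM 1.3.3 on the IWGSC 1.1 annotation of the wheat genome. CASAVA and Trimmomatic are named in the same notes without a version. The deposited TPM table held 298774 transcripts, and each library summed to 1000000 within 2. Every column was assigned to 1 sample by its name, and 0 columns were left without one. Since TPM keep no record of how many reads lie behind a value, the depth of each library is unknown, no counting interval can be given, and no count model was used. RSEM divides reads that fit several transcripts among them. In a hexaploid genome the copies of a gene on the A, B and D subgenomes can be nearly identical, so the split between such copies is an estimate and values of single copies are uncertain to that extent.

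TPM were summed over the transcripts of each gene model, which gave 269428 gene models, 107892 of high confidence and 161536 of low confidence (identifiers that end in LC). No transcript of 140712 gene models had a value above 0 in any library. Genes with at least 1 TPM in at least 4 libraries were tested, 60684 in all, of which 46155 were of high confidence. Values were analysed as log2(TPM + 1). Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values.

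Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), in 1 model with a mean for each of the 8 groups and 24 residual degrees of freedom. All limma tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison, with a threshold of 0.05. There were 17 such comparisons. They comprised 7 stress groups against control, 3 combinations with heat against heat alone, 3 single stresses averaged over the 4 backgrounds of the other stresses, and 4 departures from additivity. A departure is the log2 change of a combination less the sum of the log2 changes of its single stresses. Correlations of fold changes across genes were computed only between contrasts that share no library and tested by exact permutation of the libraries, 1225 splits, two-sided. Group differences in single measures per library were tested by exact permutation for 4 against 4 libraries, and by a permutation test with 100000 resamples within the 4 backgrounds for 16 against 16.

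Genes named in the text were taken by a rule. In each of the 7 comparisons with control, the 3 averaged effects and the 4 departures, these are the 2 gene models with the largest rise and the 2 with the largest fall past the threshold, among those with a mean of at least 5 TPM in the higher group. In comparisons with control, all 4 stressed libraries also had to lie above or below all 4 control libraries. The files pair identifiers with no gene names. A reference table of 155467 genes, made on a later wheat assembly, matched 0 of the identifiers, so gene functions are not given. Tests of gene lists by function were fixed beforehand and were not run for that reason. Chromosome and subgenome were read from the chromosome field of the identifiers, and order along a chromosome from the order of their numbers.

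The groups, the comparisons, the rule for named genes and a set of alternatives were chosen before the data were examined. The alternatives were other pseudocounts and filters, median-of-ratios scaling, quantile normalisation, removal of the 100 most abundant genes, blocks by replicate number or by the number in the sample title, a 2-fold minimum, models of the compared groups alone, and each library left out in turn. Other omissions of libraries, rescaling without low confidence gene models, and quantile normalisation without control replicate 3 were added after the data were seen. So were the medians along chromosomes, which used high confidence gene models with a mean of at least 5 TPM and compared each library with the mean of the other 3 of its group, relative to the median of all genes.

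The model was tested on simulated values drawn from the means and residual spread of the 60684 genes, with 100 genes changed at each of 2 sizes. The changed genes were taken from those with mean values of at least 5 TPM, so recovery of lower genes was not tested. For drought against control it recovered 65 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 11 calls among the other genes. For the averaged effect of salt it recovered 95 and 99 of 100, and for the departure in heat plus drought 29 and 87 of 100. These simulated libraries varied independently from gene to gene, which the real ones do not. Each gene also had the same simulated spread in every group, while real groups differed. The TPM share of the 100 most abundant gene models had an SD of 7.61 points in heat and 1.44 in heat plus drought. Recovery in the real libraries can therefore be lower, and false calls more frequent, than simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.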

Results

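Gene expression was measured in flag leaves of Stettler, a Canadian red spring wheat, to compare how the plant adjusts to heat, drought and salt alone and in combination. The flag leaf is the uppermost leaf and a main source of sugars for the filling grain. Potted plants were treated from Feekes stage 8 onward, with 8 pots per treatment. Control pots were held at 24 °C by day and 18 °C at night and watered to 100% of field capacity. Heated pots stood in a separate greenhouse at 30 °C by day, drought pots were kept at 40% of field capacity, and salt pots received sodium chloride solutions raised in steps from 20 through 40 to 80 mM. The 8 groups were control, drought, heat, salt, heat plus drought, salt plus drought, salt plus heat, and the combination of all 3 stresses, with 4 libraries each. Heat and greenhouse coincide, so these cannot be separated in any comparison of heated with unheated plants.

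Between 44106 and 53532 gene models reached 1 TPM in a library, with a median of 50870. The 100 gene models of highest mean abundance took 13.6% to 36.1% of all TPM. Their share was 20.9% ± 3.10 (SD, n = 16) with salt and 26.7% ± 5.09 (SD, n = 16) without it, a difference of -5.78 percentage points (permutation p = 0.00027, adjusted p = 0.0024 over 9 tests). It was lower with salt in each of the 4 backgrounds, with differences from -8.31 to -2.82 points. Among controls, replicate 3 stood at 33.5% and the others at 21.9% to 23.5%, against 19.5% to 22.9% with salt alone. Heat replicates 1 and 3 stood at 36.1% and 32.2%. Heat replicates 2 and 4, at 21.7% and 20.8%, lay within the 13.6% to 24.2% of salt plus heat. The differences for control and heat rest largely on control replicate 3 and heat replicates 1 and 3. With drought the ranges did not overlap (26.5% to 33.3% without salt, 17.6% to 23.9% with it). With salt, 2410 more gene models reached 1 TPM (permutation p = 0.0037, adjusted p = 0.011), and low confidence gene models held 10.1% ± 3.07 of the TPM with salt and 8.88% ± 0.56 without (SD, n = 16, permutation p = 0.002, adjusted p = 0.009). Without salt replicate 3, which stood at 21.6%, the low confidence share with salt was 9.36% ± 0.39 (SD, n = 15), a difference of 0.485 points (permutation p = 0.0054). Because TPM are relative, a smaller share for abundant genes raises the values of all others, and the median log2 change of all tested genes was 0.17 for the averaged effect of salt and -0.16 for drought against control. Counts of rises and falls, and shares of equal sign, are therefore given below both for TPM as deposited and after quantile normalisation, which gives every library the same distribution and so draws the median change toward 0 by construction.

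**Figure D1:**
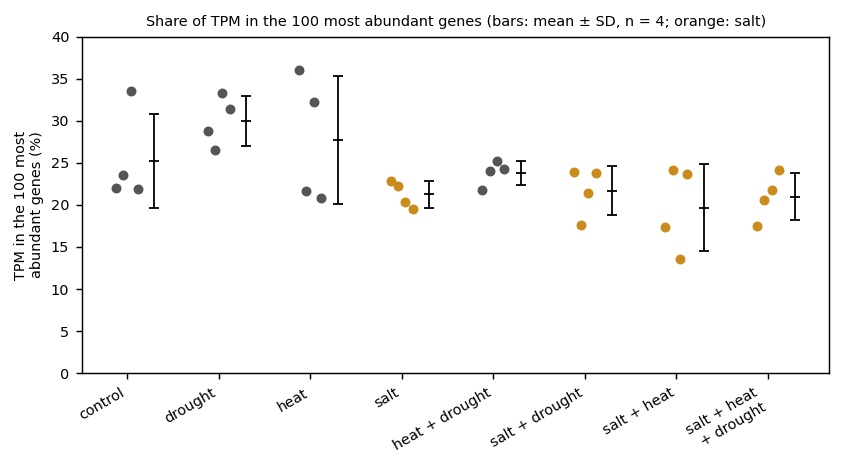
Percent of each library's TPM taken by the 100 gene models of highest mean TPM, by treatment group, with points for libraries and bars for the mean ± SD (n = 4). Salt groups, in orange, averaged 20.9% and groups without salt 26.7%; control replicate 3 stood at 33.5% and the other 3 controls between 21.9% and 23.5%.

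Several libraries stood apart from the rest of their group. Control replicate 3 had 33.5% of its TPM in the 100 most abundant gene models, against 21.9% to 23.5% in the other controls, and 44106 gene models at 1 TPM or more. The heat group split, with 36.1% and 32.2% in replicates 1 and 3 and 21.7% and 20.8% in replicates 2 and 4. These 4 libraries are the reference of each comparison with heat alone. In salt replicate 3, low confidence gene models held 21.6% of the TPM, against 9.24% to 9.83% in the other salt libraries. In salt plus heat replicate 3, the 883 gene models of chromosome 6D with at least 5 TPM had a median log2 ratio of -0.84 to the other libraries of the group, and 817 of them were lower. Lower medians also covered 100 gene models at the start of chromosome 1B in heat replicate 3 (log2 -2.93, 93 lower), 125 at the start of 6B in salt plus heat replicate 2 (log2 -0.72, 115 lower) and 176 at the end of 7A in drought replicate 4 (log2 -0.81, 167 lower). In libraries of the other groups the medians of the same 4 segments lay between -0.06 and 0.08. Of the 93 gene models of the 1B segment at 5 TPM or more in the other heat libraries, 66 were below 0.5 TPM in heat replicate 3. In drought replicate 3 a window of 25 gene models on 1A, from TraesCS1A02G184900 to TraesCS1A02G193500, was higher instead (median log2 0.836).

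**Figure D2:**
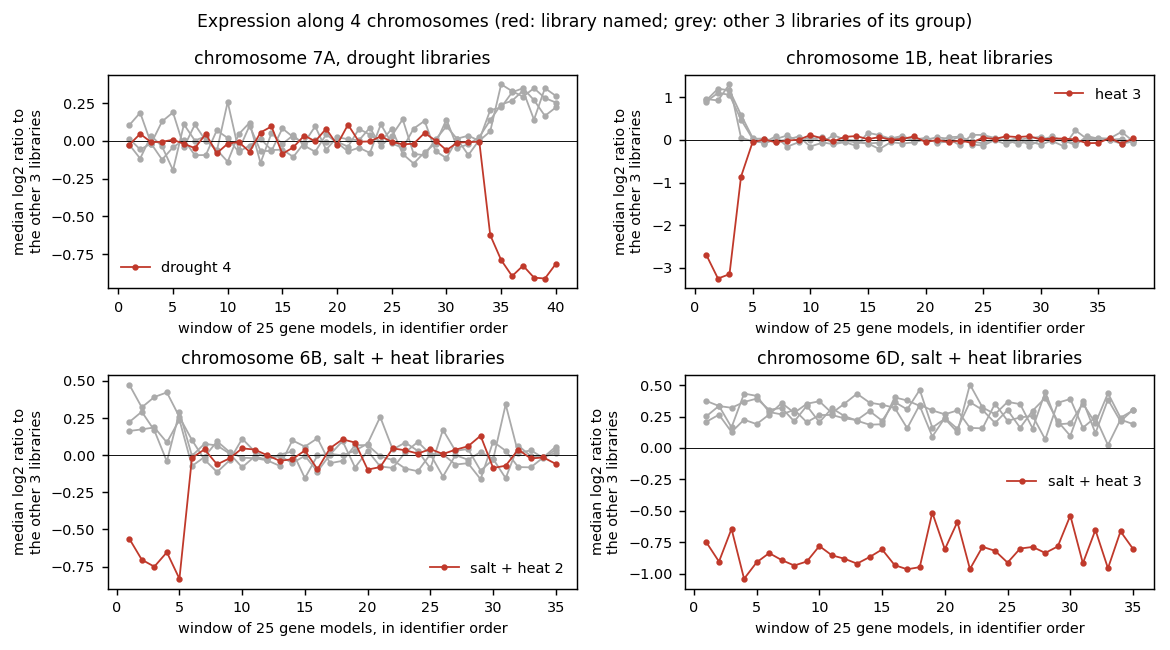
Median log2 ratio of each library to the other 3 of its group, in windows of 25 high confidence gene models in identifier order along 4 chromosomes, relative to all genes. The red library drops at the end of 7A (median -0.81), at the start of 1B (-2.93), at the start of 6B (-0.72) and along all of 6D (-0.84), while grey lines, the other 3 libraries, rise there because the red library is in their reference.

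TraesCS4D02G206200, on chromosome 4D, fell from 31.2 ± 9.27 TPM in control to 2.29 ± 1.60 TPM (SD, n = 4; log2 change -3.43, SE 0.41, adjusted p = 4.88e-05), and TraesCS3B02G010100 fell from 26.5 ± 16.0 to 2.42 ± 3.93 TPM (adjusted p = 0.0126). The low confidence model TraesCS3B02G203300LC rose from 1.33 ± 0.20 to 168 ± 143 TPM (log2 change 5.57, SE 0.82, adjusted p = 0.000685). TraesCS6B02G383600 rose from 0.34 ± 0.21 to 40.7 ± 41.1 TPM (log2 change 4.46, adjusted p = 6.63e-05). In all, 157 gene models rose and 649 fell with drought alone, of which 126 and 335 changed at least 2-fold, and 13 of the falls lay in the 7A segment that was low in drought replicate 4. After quantile normalisation 475 rose and 536 fell (240 and 226 at least 2-fold), and 154 of the rises and 425 of the falls were called under both scalings. The count of 806 became 131, 2018 and 259 without drought replicates 1, 2 and 3, 222, 184, 5886 and 181 without control replicates 1 to 4, 11 in a model of these groups alone, and 182 with the numbers in the sample titles as a block. TraesCS3B02G010100 lost its call without control replicate 1 or 4 or drought replicate 1 or 3 (adjusted p of 0.0558, 0.0743, 0.0803 and 0.06).

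TraesCS2D02G276000, on chromosome 2D, averaged below 1 TPM in each of the 4 unheated groups and rose with heat alone from 0.38 ± 0.32 TPM in control to 34.4 ± 28.1 TPM (SD, n = 4; log2 change 4.30, SE 0.41, adjusted p = 1.03e-07), and TraesCS1D02G357200LC from 4.09 ± 3.58 to 77.7 ± 31.7 TPM (log2 change 4.26, adjusted p = 4.61e-06). TraesCS5B02G408700LC fell from 92.3 ± 28.7 to 6.95 ± 2.20 TPM (log2 change -3.55, SE 0.27, adjusted p = 1.44e-09), and TraesCS6A02G085000 fell from 29.1 ± 20.1 to 0.96 ± 0.38 TPM (adjusted p = 0.00285). Control replicate 3 held 59.2 TPM of TraesCS6A02G085000 and the other controls 17.4 to 20.5 TPM. Across the genome 339 gene models rose and 397 fell (231 and 141 at least 2-fold), and 762 rose and 655 fell after quantile normalisation (292 and 146). No call changed direction between the scalings in this or any other of the 17 comparisons. Without control replicates 1, 2 and 4 the count of 736 was 460, 462 and 453, without control replicate 3 it was 1323, and a model of these groups alone gave 90.

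With salt alone TraesCS4D02G206200 fell to 0.45 ± 0.32 TPM (SD, n = 4; log2 change -4.45, SE 0.41, adjusted p = 4.84e-07), and TraesCS1D02G431200 fell from 24.4 ± 10.8 to 0.22 ± 0.28 TPM (log2 change -4.32, adjusted p = 4.84e-07). TraesCS3D02G141100 rose from 11 ± 6.10 to 391 ± 273 TPM (log2 change 4.96, SE 0.79, adjusted p = 0.000761), and TraesCS6B02G383600 rose to 34.8 ± 25.9 TPM (log2 change 4.43, adjusted p = 3.61e-05). TraesCS4D02G206200 and TraesCS6B02G383600 were also named for drought, against the same control libraries. The totals were 321 rises and 563 falls, or 179 and 379 at 2-fold or more, and 708 rises and 1235 falls after quantile normalisation (218 and 518). Leaving out 1 library lowered the count of 884 to 513, 396 and 476 (control replicates 1, 2 and 4) or 415 and 484 (salt replicates 1 and 4), and a model of these groups alone gave 329.

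Under heat plus drought TraesCS2D02G276000 reached 125 ± 51.9 TPM (SD, n = 4; log2 change from control 6.42, SE 0.41, adjusted p = 1.62e-11), which was higher than under heat alone (log2 change 2.12, adjusted p = 0.0116). Under heat alone it stood at 10.1, 68.9, 12.8 and 45.8 TPM in replicates 1 to 4, so this reference was uneven. TraesCS5D02G266000 rose from 0.54 ± 0.23 to 97.5 ± 36.5 TPM (log2 change 5.94, adjusted p = 1.23e-10). TraesCS5B02G059200 fell from 55.6 ± 7.58 to 3.66 ± 2.67 TPM (log2 change -3.79, adjusted p = 9.99e-05) and TraesCS5D02G068800 from 67.1 ± 10.6 to 4.78 ± 2.37 TPM (log2 change -3.64, adjusted p = 3.89e-06). Against control 1025 gene models rose and 543 fell, and after quantile normalisation 1372 rose and 1393 fell. Against heat alone 305 rose and 116 fell (338 and 391 after quantile normalisation). The count against control was 860 rather than 1568 without heat plus drought replicate 2. The 421 against heat became 105, 152 and 1358 without heat replicates 1, 3 and 4, 241, 86 and 180 without heat plus drought replicates 1, 2 and 4, and 5 in a model of these groups alone.

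The 4 gene models named for salt alone were also those with the largest changes in salt plus drought, against the same control libraries. TraesCS6B02G383600 rose to 35.9 ± 16.7 TPM (SD, n = 4; log2 change 4.67, adjusted p = 2.15e-05) and TraesCS3D02G141100 to 235 ± 107 TPM (log2 change 4.38, adjusted p = 0.00327). TraesCS1D02G431200 fell to 0.61 ± 0.71 TPM and TraesCS4D02G206200 to 1.26 ± 1.19 TPM (adjusted p = 3.24e-06 for both). In total 596 gene models rose and 488 fell. Quantile normalisation gave 772 rises and 1316 falls. Without salt plus drought replicates 1, 2 and 3 the count of 1084 was 459, 306 and 524, without control replicates 1, 2 and 4 it was 578, 495 and 621, and with the title numbers as a block 520.

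Under salt plus heat TraesCS2D02G276000 reached 193 ± 70.1 TPM (SD, n = 4; log2 change 7.06, SE 0.41, adjusted p = 1.98e-12), again above heat alone (log2 change 2.76, adjusted p = 0.000288). The reference was the same uneven heat group. TraesCS3D02G346300 rose from 0.17 ± 0.15 to 211 ± 193 TPM (log2 change 7.05, SE 0.79, adjusted p = 6.75e-07). TraesCS2A02G052500 fell from 60 ± 17.9 to 1.91 ± 1.13 TPM (log2 change -4.43, SE 0.53, adjusted p = 2.15e-06) and TraesCS5B02G059200 to 3.22 ± 2.12 TPM (log2 change -3.95, adjusted p = 3.48e-05). Against control 4253 gene models rose and 1520 fell, and after quantile normalisation 3279 rose and 3382 fell, with 2946 rises and 1501 falls called under both. Against heat alone 5883 rose and 857 fell, or 2100 and 2097 after quantile normalisation. The 5773 calls against control became 3336 without control replicate 3, 2904 and 2873 without salt plus heat replicates 1 and 3, the latter being the library with low 6D values, and 1375 in a model of these groups alone. The 6740 against heat became 1641, 2120 and 11196 without heat replicates 1, 3 and 4, 1693 and 1950 without salt plus heat replicates 1 and 3, 24 in a model of these groups alone, and 4110 with the title numbers as a block.

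All 3 stresses together gave 5874 rises and 2401 falls against control, of which 1579 and 1049 were at least 2-fold. TraesCS4D02G134900 rose from 3.56 ± 2.91 to 602 ± 295 TPM (SD, n = 4; log2 change 7.22, SE 1.08, adjusted p = 5.92e-05) and TraesCS3D02G346300 to 108 ± 44.3 TPM (log2 change 6.48, adjusted p = 3.38e-06). TraesCS2A02G052500 fell to 0.33 ± 0.25 TPM (log2 change -5.50, SE 0.53, adjusted p = 8.62e-08), and TraesCS6D02G054900 fell from 93.2 ± 52.9 to 1.9 ± 1.3 TPM (log2 change -4.84, adjusted p = 0.000113). TraesCS2D02G276000 stood at 69.7 ± 7.68 TPM, above heat alone (log2 change 1.40, adjusted p = 0.0216). The lowest triple stress library held 60.8 TPM of it, less than heat replicate 2 with 68.9 TPM. After quantile normalisation 4920 gene models rose and 5342 fell (1045 and 1477 at least 2-fold), with 4279 rises and 2377 falls called under both scalings. Against heat alone the counts were 7430 and 1606, or 4048 and 4063 after quantile normalisation. Without control replicate 3 the 8275 calls against control became 5379, without replicate 1 of the triple stress 4825, and with at least 5 TPM required in at least 4 libraries 5394. The 9036 against heat became 3897 and 4816 without heat replicates 1 and 3, 4612 and 5435 without replicates 1 and 2 of the triple stress, and 3801 in a model of these groups alone.

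**Figure D3:**
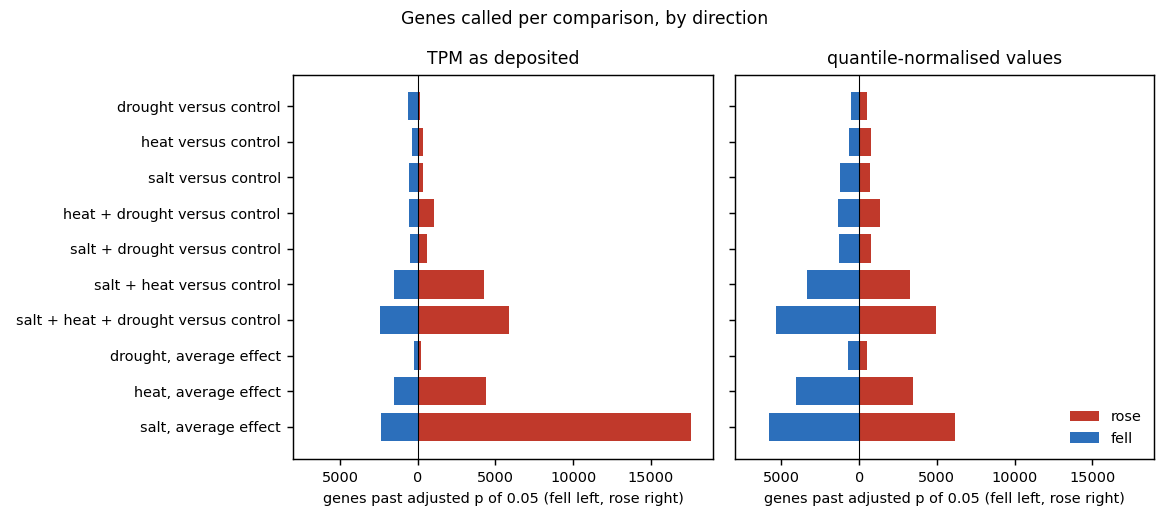
Gene models past an adjusted p of 0.05 that fell (blue, left of 0) or rose (red, right of 0) in 7 comparisons with control and 3 averaged effects, for TPM as deposited and after quantile normalisation. With the deposited values salt, averaged over backgrounds, gave 17569 rises and 2395 falls; after quantile normalisation it gave 6179 and 5778.

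Of the 339 gene models raised by heat alone, 37 were higher and 103 lower under the triple stress than under heat (25 and 154 after quantile normalisation). Under heat plus drought 35 were higher and 20 lower, and under salt plus heat 73 were higher and 49 lower. Quantile normalisation gave 37 and 35 for heat plus drought and 61 and 81 for salt plus heat, so the balance for salt plus heat depended on the scaling. Of the 397 lowered by heat alone, 131 were higher and 20 lower under the triple stress than under heat (82 and 40 after quantile normalisation), 43 and 2 under heat plus drought (29 and 3), and 107 and 15 under salt plus heat (29 and 22). The heat libraries served both to pick these genes and as the reference, which by itself pulls the second comparison toward lower values for the raised set and higher values for the lowered set.

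Averaged over the 4 backgrounds, heat raised TraesCS2D02G276000 by 5.75 on the log2 scale (SE 0.20, adjusted p = 6.59e-18) and TraesCS5D02G266000 by 5.14 (SE 0.21, adjusted p = 1.10e-16). TraesCS5D02G068800 and TraesCS5B02G059200 fell by 2.24 (adjusted p = 3.01e-08 and 2.89e-06). Heat gave 4379 rises and 1549 falls, or 3487 and 4040 after quantile normalisation. Under salt TraesCS2A02G052500 fell by 3.03 (SE 0.27) and TraesCS1B02G350800 fell by 2.67 (SE 0.19) on the log2 scale (adjusted p = 2.43e-08 and 1.14e-09). Salt raised TraesCS2D02G253900 by 2.98 (adjusted p = 0.000152) and TraesCS6B02G383600 by 2.97 (adjusted p = 6.96e-08). Salt gave 17569 rises and 2395 falls, of which 329 and 192 were at least 2-fold. After quantile normalisation there were 6179 rises and 5778 falls (195 and 280 at least 2-fold), with 6167 rises and 2289 falls called under both scalings. For heat and for salt no single library moved the count by 1.5 times, but the 5928 for heat became 2732 with the title numbers as a block and 3936 with at least 5 TPM required in at least 4 libraries. The 19964 for salt became 13113 without the 100 most abundant gene models.

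Drought had the smallest averaged effect, with 233 rises and 253 falls (28 and 22 at least 2-fold). TraesCS3B02G203300LC rose by 2.31 on the log2 scale (SE 0.41, adjusted p = 0.0063) and TraesCS2B02G490400 by 1.97 (SE 0.43, adjusted p = 0.023). TraesCS6B02G063900 fell, with a log2 change of -1.95 (SE 0.43, adjusted p = 0.0259), as did TraesCS6D02G054900 with -1.89 (SE 0.38, adjusted p = 0.0142). The last 2 lie in segments that were low in 1 salt plus heat library each, on the side without drought, which makes these falls smaller. In salt plus heat replicate 1 they stood at 64.1 and 84.6 TPM, against 0.13 to 3.1 and 3.12 to 8.62 TPM in the others of that group. TraesCS6B02G063900 averaged 32.7 TPM in control and 2.3 in drought, 31.1 in heat and 3.01 in heat plus drought, but 1.72 in salt and 1.84 in salt plus drought. Quantile normalisation gave 512 rises and 740 falls (33 and 32 at least 2-fold), and median-of-ratios scaling 491 and 867. The count of 486 became 22 with the title numbers as a block, and leaving out 1 library moved it by over 1.5 times for 13 of 32 libraries, between 224 without heat plus drought replicate 2 and 884 without salt plus heat replicate 3. TraesCS2B02G490400 lost its call without heat plus drought replicate 2 (adjusted p = 0.0505), and TraesCS6B02G063900 without that library, drought replicate 1 or salt replicate 4 (adjusted p of 0.055, 0.0507 and 0.0527).

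**Figure D4:**
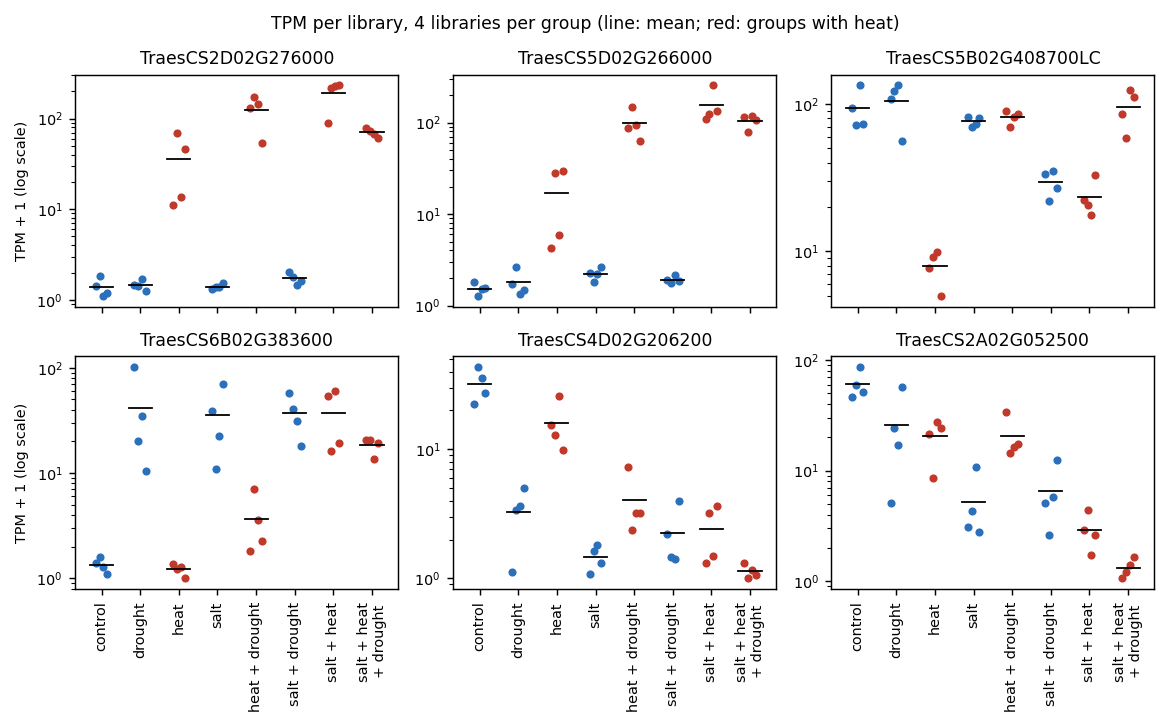
TPM + 1 of 6 named gene models on a log axis, 4 libraries per group (points), with a line at the arithmetic mean and heated groups in red. TraesCS2D02G276000 averaged 0.38 TPM in control and 34.4, 125, 193 and 69.7 TPM in heat, heat plus drought, salt plus heat and the triple stress; TraesCS5B02G408700LC averaged 6.95 TPM under heat alone and 80.4 TPM under heat plus drought.

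In heat plus drought 192 gene models lay above and 7 below the sum of the single stresses. The median departure of all tested genes was 0.318, and 0.0275 after quantile normalisation, so a shift of whole libraries enters this balance. Under both scalings 41 of the 192 and all 7 were called. A log2 of TPM + 1 cannot be below 0, so where the sum is below 0 the combination has to lie above it, and this held for 11 of the 192. TraesCS4B02G219500 averaged 11.7 ± 2.75 TPM in control, 4.26 ± 2.92 in drought, 1.33 ± 0.77 in heat and 12.6 ± 1.13 in the combination (SD, n = 4, departure 4.20, SE 0.66, adjusted p = 0.00591), with a sum of -0.44 and 3.77 observed. TraesCS2A02G493400 departed by 3.41 (adjusted p = 0.0246), and TraesCS4A02G116800 and TraesCS4D02G189000 by -1.37 and -1.25 (adjusted p = 0.00743 and 0.022). TraesCS5B02G408700LC, named for heat alone and singled out here after its values were seen, stood at 80.4 ± 8.06 TPM in heat plus drought and departed by 3.25 (SE 0.38, adjusted p = 0.000131). In salt plus heat 15 lay above and 13 below the sum, which was below 0 for 2 of the 15. TraesCS5A02G257700 and TraesCS5B02G257000 departed by 3.85 and 3.51 (adjusted p = 0.0056 and 0.00401), with 81.3 ± 34.6 and 99.5 ± 36.9 TPM in the combination against 5.30 ± 5.23 and 8.42 ± 6.74 under heat. In heat replicates 1 to 4 TraesCS5A02G257700 stood at 0.9, 10.1, 0.67 and 9.54 TPM. The adjacent models TraesCS7D02G516700 and TraesCS7D02G516800 departed by -2.66 and -2.34 (adjusted p = 0.0238 and 0.0448).

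In salt plus drought 56 gene models lay above and 8 below the sum, but for 31 of the 56 the sum was below 0 and the direction fixed in advance. These include TraesCS4D02G206200 and TraesCS1D02G431200, at or below 2.29 TPM under each of these stresses, with sums of -2.92 and -3.01 and departures of 3.97 and 3.61 (adjusted p = 0.00576 and 0.00901). TraesCS6B02G383600 and TraesCS7B02G209600, raised by each stress, departed by -4.22 and -2.79 (adjusted p = 0.0249 and 0.00744). For the triple stress 18 lay above and 1 below, and for 10 of the 18 the sum was below 0. The largest, TraesCS1D02G430700 (departure 4.03, adjusted p = 0.00722) and TraesCS1A02G422900 (3.81, adjusted p = 0.0212), are among these, with sums of -3.63 and -3.56. The median departure of all tested genes was also above 0 in salt plus heat (0.196), salt plus drought (0.246) and the triple stress (0.347). After quantile normalisation the gene models above and below the sum numbered 45 and 39 for heat plus drought, 6 and 24 for salt plus heat, 47 and 39 for salt plus drought, and 22 and 30 for the triple stress. Of those above the sum as deposited, 5 of 15 in salt plus heat, 35 of 56 in salt plus drought and 12 of 18 in the triple stress were called under both scalings. Leaving out 1 library moved the count from 199 to between 18 (heat replicate 1) and 8862 (control replicate 3) for heat plus drought, from 64 to between 7 (salt plus drought replicate 4) and 2820 (control replicate 3) for salt plus drought, from 28 to between 10 and 56 (salt plus heat replicates 4 and 1), and from 19 to between 2 and 315 (control replicates 2 and 3) for the triple stress. With the title numbers as a block the counts were 15 for heat plus drought, 11 for salt plus heat and 2 for the triple stress, and with at least 5 TPM required in at least 4 libraries 586 for heat plus drought and 8 for the triple stress. The departures of TraesCS5A02G257700, TraesCS5B02G257000, TraesCS7D02G516800, TraesCS4D02G206200, TraesCS1D02G431200, TraesCS1D02G430700 and TraesCS1A02G422900 kept their sign but not their call with a pseudocount of 0.1 (adjusted p from 0.0581 to 0.296). Leaving out 1 library also ended calls, in 8 of 16 fits for TraesCS2A02G493400, 5 of 16 for TraesCS4D02G189000, 6 of 16 for TraesCS7D02G516700, 9 of 16 for TraesCS7D02G516800, 6 of 16 for TraesCS6B02G383600, 2 of 20 for TraesCS1D02G430700 and 5 of 20 for TraesCS1A02G422900. The highest adjusted p among these was 0.172, for TraesCS1A02G422900 without control replicate 2.

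Log2 changes with and without heat were compared across genes, between contrasts with no library in common. Salt effects correlated at r = 0.48 (Spearman rho 0.42; exact permutation p = 0.00163, adjusted p = 0.00652 over 4 relations), and 66% of gene models had the same sign of change in both (64.7% after quantile normalisation). Salt plus drought effects correlated at r = 0.51 (rho 0.47; exact permutation p = 0.0049, adjusted p = 0.0098), with the same sign for 75.2% (67.7%). Drought effects with and without heat gave r = 0.14 (rho 0.06; exact permutation p = 0.411), and heat effects with and without drought r = 0.14 (rho 0.05; exact permutation p = 0.287), neither past the threshold (adjusted p = 0.411 and 0.383), with the same sign for 38.5% and 42.2% (51.9% and 51.6% after quantile normalisation). A shift of all values between libraries moves these shares, and the median log2 change was -0.16 for drought against control and 0.16 for heat plus drought against heat. Genes are not independent replicates, so these p-values come from permuting libraries.

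The largest difference in a subgenome's share of TPM between a stress group and control was 1.24 percentage points, for the A subgenome under salt, 31.8% ± 1.95 against 33.1% ± 0.27 (SD, n = 4; exact permutation p = 0.2, adjusted p = 0.6). Of 21 exact permutation tests, 0 passed the adjusted threshold and 4 had an unadjusted p below 0.05, where the smallest p that 4 against 4 libraries allow is 0.0286. That 1.24 came from salt replicate 3, at 28.9%. Without it the A share under salt was 32.8% ± 0.29 (SD, n = 3), a difference of -0.276 points, and the largest difference was 0.53 points, for the B subgenome under salt plus heat (exact permutation p = 0.229). There replicate 3, the library with low 6D values, stood at 31.95% and the others of its group between 30.47% and 31.03%. Adjusted over 21 tests, that smallest p reaches the threshold only if most of the tests share it, so differences of this size could hardly have passed.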

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

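The tests on the salt rises, the test of a library state in control replicate 3, the tests of treatment and of moved reads for chromosome 6D, the counts of additive sums below 0, and the counts of other splits for drought, heat and averaged salt were chosen after the result was seen.

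Within groups, 14 sets of 4 libraries had 1 library far from the rest by Dixon's gap test, where chance gives about 1 in 20 of the sets tested, or 5.05. The test looks for 1 library apart. It could not flag the heat group, where replicates 1 and 3 stood apart from replicates 2 and 4 in the share of the 100 most abundant. Control replicate 3 had 44106 gene models at 1 TPM or more (others 50218 to 51289), 7.8% of its TPM in low confidence models (others 9.39% to 9.51%), 33.5% in the 100 most abundant (others 21.9% to 23.5%), and 59.2 TPM of TraesCS6A02G085000 (others 17.4 to 20.5). Salt plus drought replicate 2 had 52953 gene models at 1 TPM or more (others 50717 to 51099). In salt replicate 3 low confidence models held 21.6% of the TPM (others 9.24% to 9.83%), the A, B and D subgenomes 28.9%, 26.8% and 37.6% (others 32.5% to 33.1%, 30.7% to 31% and 34.3% to 34.4%), and chromosome 6D 2.81% (others 3.56% to 3.65%). In that library 20 low confidence gene models held 12.8% of the TPM, and without them the low confidence share was 10.1%. Its 883 gene models of 6D with a mean of at least 5 TPM had a median log2 ratio of 0.008 to the other salt libraries, relative to all genes. As a set they were thus not low in salt replicate 3. Salt plus heat replicate 3 had 2.14% of its TPM on 6D (others 3.51% to 3.73%). TraesCS1D02G431200 stood at 0.64 TPM in salt replicate 2 (others 0.06 to 0.11) and 1.66 TPM in salt plus drought replicate 4 (others 0.19 to 0.3), and TraesCS2D02G276000 at 88.3 TPM in salt plus heat replicate 1 (others 219 to 234).

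Effects that differed between backgrounds were taken from the departures from additivity in limma. They numbered 199 in heat plus drought, with TraesCS4B02G219500 at 4.20, TraesCS2A02G493400 at 3.41, TraesCS4A02G116800 at -1.37 and TraesCS4D02G189000 at -1.25. In salt plus heat they numbered 28, with TraesCS5A02G257700 at 3.85, TraesCS5B02G257000 at 3.51, TraesCS7D02G516700 at -2.66 and TraesCS7D02G516800 at -2.34. In salt plus drought they numbered 64, with TraesCS4D02G206200 at 3.97, TraesCS1D02G431200 at 3.61, TraesCS6B02G383600 at -4.22 and TraesCS7B02G209600 at -2.79. In the triple stress they numbered 19, with TraesCS1D02G430700 at 4.03 and TraesCS1A02G422900 at 3.81. A positive sign is forced where the additive sum is below 0, as for 11, 2, 31 and 10 of those in the 4 combinations in this order, among them TraesCS4B02G219500, TraesCS4D02G206200, TraesCS1D02G431200, TraesCS1D02G430700 and TraesCS1A02G422900. For TraesCS4B02G219500 the sum was -0.44 and 3.77 was observed, so little of its departure of 4.20 is forced.

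Against control, the real split gave the most genes of 35 splits of the same 8 libraries for heat plus drought (1568 genes, highest other split 12), salt plus drought (1084, highest other 1), salt plus heat (5773, highest other 4) and the triple stress (8275, highest other 11). So it did for the triple stress against heat (9036, highest other 5). First of 35 is the strongest result that these splits allow, and it was not adjusted over the comparisons. It argues against chance there without excluding it. For averaged drought (486, highest other 167), heat (5928, highest other 12) and salt (19964, highest other 3599), the real count was the largest of 100 splits. Those splits shuffled all 32 libraries, so effects of the other stresses entered their spread, which can lower their counts. They therefore cannot exclude chance for 1 stress. For departures in salt plus drought 4 of 100 splits gave at least 64 (highest other 8544), which passed the limit set beforehand. Splits for departures mixed the groups of the contrast, single-stress effects included, so they cannot exclude chance for a departure. Another split gave more genes, and chance stays open, for drought (2 of 35 splits gave at least 806, highest other 15835), heat (6 of 35, 736 against 12884), salt (2 of 35, 884 against 918), heat plus drought against heat (2 of 35, 421 against 500) and salt plus heat against heat (2 of 35, 6740 against 12085). The same held for departures in heat plus drought (5 of 100, 199 against 17429), salt plus heat (10 of 100, 28 against 16112) and the triple stress (6 of 100, 19 against 6013). In drought and heat, splits that call many times the real number point to a structure of the samples other than their groups. In both, the split with the most calls parted the libraries by the share of the 100 most abundant gene models. The 2 sides held 21.9% to 26.5% and 28.8% to 33.5% for drought, and 20.8% to 22.0% and 23.5% to 36.1% for heat. In the 4 departures, splits with many calls can also arise from single-stress effects, so by themselves they point to no such structure.

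Salt rises outnumbered falls by 17569 to 2395 in deposited TPM. The share of the 100 most abundant gene models was lower with salt (permutation p = 0.00027), but these genes alone are argued against as the whole cause, since without them and with the rest rescaled 72.9% of salt calls were still rises. A smaller share for abundant genes in general stays open, because quantile normalisation, which left 51.7% as rises, draws that balance to even by construction and decides nothing. TPM hold no external standard, so whether other transcripts rose in absolute amount or abundant ones fell was not measured. An effect of salt on these transcripts also stays open.

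Exchanging control replicate 3 and drought replicate 2 gave the split with 15835 genes, against 806 for the real one. A swap of these libraries is argued against by 64 drought genes chosen from the other 24 libraries, on which control replicate 3 lay at -0.237 and drought replicate 2 at 1.05, with the other controls averaging 0 and the other drought libraries 1. A library state in which abundant genes take more of the TPM is a candidate explanation, since leaving out control replicate 3 multiplied the count by 7.3 in deposited TPM and by 1.65 after quantile normalisation. It may not be the whole, because the exchange still gave 3150 genes against 1011 after quantile normalisation. No biological explanation was tested, as the labels give none that differs within a group.

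Chromosome 6D gene models were lower in salt plus heat replicate 3, and fewer of them rose with averaged salt (odds ratio 0.429). The treatment is argued against by the other 3 libraries of that group, whose 6D median against control was -0.012, and reads moved to copies on 6A and 6B by medians there of at most 0.038. The loss of 1 of the 2 copies of 6D in that plant is a candidate explanation, since the medians of 10 consecutive parts of the chromosome lay between -0.937 and -0.696, near the -1 of 1 copy, though the chromosome-wide median was known beforehand. That library had the 6D median farthest from its group mean among the 32 (-0.633), and without it the odds ratio for salt rises was 1.06. A mixed or mislabelled plant, and the origin of the 1B, 6B and 7A segments in other libraries, were not tested, and the 1B median of -2.93 is too low for the loss of 1 of 2 copies.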

How the results depend on the processing

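Joint omission of control replicate 3, drought replicate 2 and salt replicate 3, omission of the library with low chromosome 6D values, rescaling without low confidence gene models, quantile normalisation without control replicate 3, same-sign shares after quantile normalisation, pairs of neighbours without segment libraries or segment genes, and library shares without salt replicate 3 were chosen after the data were seen. TPM carry no read numbers, so the counting error of low genes is unknown and no limit of detection can be given. Of the 54 results for named gene models, 0 reversed under median-of-ratios scaling, quantile normalisation, a pseudocount of 0.1, the replicate block or omission of 1 library. Calls were lost for 7 of the 54 with a pseudocount of 0.1 and for 0 under both scalings and the replicate block. Without 1 library, calls were lost in 4 of 224 fits for comparisons with control (1 of 28 results), 4 of 384 for averaged effects (2 of 12) and 41 of 232 for departures (7 of 14). The correlations kept their direction and their side of the threshold under each alternative run. The same-sign shares moved from 38.5% to 51.9% for drought and from 42.2% to 51.6% for heat after quantile normalisation. Apart from the ranges in the last paragraph, the counts that follow moved by more than 1.5 times, and except where stated the cause was not tested.

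With a pseudocount of 0.1 departures numbered 10 in salt plus heat, 5 in salt plus drought and 1 in the triple stress, and with a pseudocount of 5 there were 37 in the triple stress. With no filter on low values the counts were 4285 for salt plus heat against heat and 271 for averaged drought. Departures were then 103 in heat plus drought, 17 in salt plus heat and 34 in the triple stress. With at least 5 TPM in at least 4 libraries they were 5394 for the triple stress against control, 3936 for averaged heat, and 586 and 8 for departures in heat plus drought and the triple stress.

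Median-of-ratios scaling gave 1519 genes for heat, 2131 for salt, 2989 for heat plus drought and 2087 for salt plus drought against control. Against heat it gave 741 for heat plus drought and 4248 for salt plus heat, and on average 1358 for drought and 12022 for salt. Departures numbered 127 in heat plus drought, 97 in salt plus drought and 56 in the triple stress. Quantile normalisation gave 1417 for heat, 1943 for salt, 2765 for heat plus drought and 2088 for salt plus drought against control. Against heat it gave 729 for heat plus drought and 4197 for salt plus heat, and on average 1252 for drought and 11957 for salt, with 84 and 52 departures in heat plus drought and the triple stress. Without the 100 most abundant genes the counts were 1373 for salt against control, 4229 for salt plus heat against heat, 767 for averaged drought and 13113 for averaged salt. Departures were 73 in heat plus drought, 105 in salt plus drought and 29 in the triple stress.

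The replicate numbers do not pair the samples, since 27 of 112 pairs of equal number had deviations correlated above 0.1 (range -0.292 to 0.293) and in 0 of 28 pairs of groups did all of them. With the replicate block, departures numbered 449 in heat plus drought and 127 in salt plus drought, and the other 15 counts stayed within 1.5 times. For the numbers in the sample titles 14 of 56 pairs were above 0.1 (range -0.467 to 0.47). As a block these gave 182 genes for drought and 520 for salt plus drought against control, 4110 for salt plus heat against heat, 22 for averaged drought and 2732 for averaged heat. Departures were 15 in heat plus drought, 11 in salt plus heat and 2 in the triple stress.

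A minimum of 2-fold lowers counts by construction. It left 461 genes for drought, 372 for heat, 558 for salt, 768 for heat plus drought, 561 for salt plus drought, 2142 for salt plus heat and 2628 for the triple stress against control. Against heat it left 203 for heat plus drought, 1467 for salt plus heat and 2378 for the triple stress. It left 50, 375 and 521 for averaged drought, heat and salt, and 132 departures in heat plus drought. Models of the compared groups alone have fewer libraries to estimate the spread. They also use the spread of those groups only, where the shared model takes 1 spread per gene for all groups. The share of the 100 most abundant gene models had an SD of 7.61 points in heat and 1.44 in heat plus drought. For the more variable groups the shared model can thus give p-values that are too small. Models of the compared groups gave 11 genes for drought, 90 for heat, 329 for salt and 1375 for salt plus heat against control. Against heat they gave 5 for heat plus drought, 24 for salt plus heat and 3801 for the triple stress.

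Without control replicate 3, drought replicate 2 and salt replicate 3 the counts were 12760 for drought, 1763 for heat and 3797 for salt plus heat against control. Drought replicate 2 was not flagged by the gap test, and heat replicates 1 and 3, which did stand apart, were kept. Leaving out control replicate 3 or drought replicate 2 alone already raised the 806 for drought, to 5886 and 2018, so the 12760 is no independent check. They were 951 for heat plus drought and 10504 for salt plus heat against heat, and 1079 for averaged drought. Departures were 15341 in heat plus drought, 1836 in salt plus drought and 1511 in the triple stress. Without salt plus heat replicate 3 the counts were 2873 for salt plus heat against control, 1950 against heat, 884 for averaged drought and 18 departures in salt plus heat. Rescaling to high confidence gene models gave 364 departures in heat plus drought. Quantile normalisation without control replicate 3 gave 1665, 1402 and 1513 genes for drought, heat and salt against control, 1258 and 10448 for averaged drought and salt, and 366, 278 and 57 departures in heat plus drought, salt plus drought and the triple stress.

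With 1 library left out, counts against control ranged from 131 to 5886 for drought, 453 to 1323 for heat, 396 to 1290 for salt, 860 to 1376 for heat plus drought and 306 to 1097 for salt plus drought. They ranged from 2873 to 7464 for salt plus heat and 4825 to 7653 for the triple stress. Against heat the ranges were 86 to 1358 for heat plus drought, 1641 to 11196 for salt plus heat and 3897 to 12926 for the triple stress. Averaged effects ranged from 224 to 884 for drought, and within 1.5 times from 4854 to 8436 for heat and 16079 to 23321 for salt. Departures ranged from 18 to 8862 in heat plus drought, 10 to 56 in salt plus heat, 7 to 2820 in salt plus drought and 2 to 315 in the triple stress. Correlations ranged from 0.0482 to 0.228 for drought, 0.392 to 0.499 for salt, 0.421 to 0.544 for salt plus drought, and 0.0393 to 0.231 for heat with and without drought.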

Other observations

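The runs of neighbouring gene models and the transcripts named here were chosen after their values were seen, while the tests were fixed before their results, except the repeats without segment libraries or segment genes, which were added after.

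Gene models next to each other on a chromosome were called in the same direction more often than in any shuffling of the calls for both directions of heat and salt, while drought depended on the libraries used. After quantile normalisation, 274 of 41986 adjacent pairs of high confidence gene models rose together with averaged heat, where 1000 shufflings of the calls gave at most 213, and 333 fell together (at most 305). With averaged salt 727 pairs rose together (at most 668) and 706 fell (at most 588). With averaged drought 27 fell together (at most 19), while 7 rose together, within the range of the shufflings (at most 12). Stretches of neighbours were low in drought replicate 4 (7A), heat replicate 3 (1B) and salt plus heat replicates 2 (6B) and 3 (6D). Without these 4 libraries the pairs were 193 and 196 for rises and falls with heat (at most 134 and 186), 356 and 372 with salt (at most 313 and 292), and 19 and 32 with drought (at most 16 and 37). With all libraries but without the genes of the 4 segments they were 266 and 310 with heat (at most 208 and 293), 713 and 646 with salt (at most 654 and 556), and 7 and 27 with drought (at most 10 and 22). Under heat 6 gene models on 3B, from TraesCS3B02G130300 to TraesCS3B02G131300, rose with log2 changes of 1.67 to 4.59 (median 3.28). Under salt 7 on 6A, from TraesCS6A02G093700 to TraesCS6A02G094600, fell with log2 changes of -1.84 to -1.12 (median -1.38). Whether near-identical neighbours share reads was not tested.

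The share of a gene's TPM held by each of its transcripts was compared in limma for 2133 genes with at least 5 TPM in every library. With averaged heat 24 genes had a transcript share changed by at least 10 points past the adjusted threshold, the most of 100 splits of the 32 libraries (highest other 2), and with salt 8 (highest other 1). With drought 0 did, and 0 at any size, as against 58 and 23 at any size for heat and salt. The splits mixed the other stresses as well, which can lower their counts. Transcript 3 of TraesCS3D02G333400 held 53.8% ± 6.67 of the gene's TPM with heat and 35% ± 6.64 without (SD, n = 16, limma adjusted p = 4.82e-05). Transcript 2 of TraesCS5A02G100100 held 37.5% ± 9.82 with salt and 23.5% ± 7.13 without (SD, n = 16, limma adjusted p = 1.11e-05). RSEM divides reads shared by transcripts, so these shares are estimates.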
